A study of Arabidopsis thaliana with 12 samples.

How the data were processed

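The values analysed were the spot intensities the authors deposited for 12 array samples, 6 of WT and 6 of tpt1, on a linear scale from 0 to 100. The label of each sample gave its group and its number from 1 to 6. How the spots were read, corrected for background and scaled is not given in the sources used here, nor are the tissue, the growth conditions or the kind of label on the RNA. So the scale, the centring and the handling of low signals before deposit stay unknown, and a reading of 0 may be a true absence or a value set to 0. In each WT sample 4 to 7 spots reached the ceiling, and in each tpt1 sample 0 or 1. Of the 7 spots with a reading at the ceiling in any sample, 3 were there in all WT samples, 1 was called and 0 were annotated to a single gene. The number of arrays limits the precision.

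Zeros were set as missing and the values taken as log2. The rule fixed for the normalization was to keep the deposited scale where the medians of the samples lay within 0.1 of each other on the log2 scale and to quantile normalize otherwise, and the medians lay further apart. A spot was tested when it had at least 4 values above 0 in each group, which 2849 of 3439 spots had. The test was limma (lmFit and eBayes with a trend in the prior variance, version 3.58.1, with statmod 1.5.0 in R 4.3.3), with Benjamini-Hochberg adjustment over all tested spots and a threshold of 0.05. Its errors are the moderated standard errors. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

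Genes were named from the platform annotation, with symbols and loci taken through the gene identifiers from a reference table of assembly TAIR10.1, which was used for names only. Of the 692 spots with 1 gene, 690 matched a locus. AT2G25870 had 2 such spots that differed in call, with log2 changes of 1.20 (adjusted p = 0.0291) and 0.38 (adjusted p = 0.286). With the sample number as a block both passed (adjusted p = 0.00474 and 0.0245), and with averaged neighbours and the set as a block the second did not (adjusted p = 0.144). Spots were tested singly. No coordinates are given, since the build used by the authors is not given in the sources used here.

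The design, the alternatives, the 25 gene lists (393 loci of plastid pathways, of cytosolic sugar metabolism and of markers of other tissues) and the rule for naming genes were fixed before the data were examined. The rule names TPT and each measured gene of the envelope transporter list. It also names the 10 largest rises and the 10 largest falls in log2 with an adjusted p under 0.05 on a spot with 1 gene, and for each list its called genes, at most the 2 with the smallest adjusted p. The planned check of the TPT transcript could not be made. Lists with at least 3 tested genes were tested with camera on the 2383 spots with values in all samples, at its preset correlation of 0.01, and with an estimated correlation, on ranks and with fry.

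The sample numbers were checked as pairs before the calls of the fits were compared. After subtraction of the group means, samples with the same number correlated across spots at 0.42 to 0.56, and 12 of 12 samples correlated best with their own number in the other group. By the rule used, that every pair lies above 0.1, the numbers pair the samples; the labels themselves do not say what a number marks. The unpaired fit stayed the main one, as fixed, and the fit with the number as a block is given where it changes a call. Other alternatives were the deposited scale, median centring, a filter, a pseudocount, random blocks, array weights, other prior variances, an exact rank-sum test and stricter thresholds. Further ones that use sets of neighbouring numbers were added after the correlations had been seen.

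The fits were tested on simulated data for tpt1 against WT over 2849 spots, with the spread of the real data and 200 changed spots. The unpaired fit found 52 of 100 spots changed by 1 on the log2 scale and 81 of 100 changed by 2, with 0 false calls. The fit with the number as a block found 71 and 90 of 100, with 11 false calls.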

Results

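Transcript levels were compared between wild-type (WT) Arabidopsis thaliana and the tpt1 mutant, both of ecotype Wassilevskija. The labels describe tpt1 as a mutant with strongly reduced transport of triose phosphate in its chloroplasts. The triose phosphate/phosphate translocator (TPT) of the chloroplast envelope exports the carbon fixed by photosynthesis to the cytosol in exchange for phosphate. Total RNA of 6 WT and 6 tpt1 samples, numbered 1 to 6 in each group, was measured on an expression array with 3439 spots. The labels do not say whether the samples of a group came from separate plants, so the p-values may measure only technical spread. With neighbouring numbers of a group as a random block, the correlation within a block was 0.63. It was 0.1 once the sets of neighbouring numbers were also fitted. After subtraction of the group means, neighbours correlated across spots at -0.07 to 0.25 in WT and 0.12 to 0.58 in tpt1. That subtraction pulls correlations within a group below 0, so values near 0 do not show independence. WT 3 was at -0.07 with WT 4, against -0.096 to -0.377 with the other WT samples. The 6 samples of a group may therefore not be 6 independent replicates, and p-values that take n as 6 may be too small. Of the spots, 692 were annotated to 1 gene, 870 to several genes and 1877 to none, and genes are named only from the first kind. No spot carried an annotation to TPT itself, so the level of its transcript, which would check the labels, was not analysed here.

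The deposited intensities ran from 0 to a ceiling of 100 and differed in distribution between the 2 groups. The median log2 intensity of the spots above 0 lay between -2.38 and -1.72 in the WT samples and between -1.42 and -0.88 in the tpt1 samples. Medians of neighbouring numbers lay close in WT, at -1.734 (WT 1) and -1.715 (WT 2), -1.899 (WT 3) and -1.912 (WT 4), and -2.382 (WT 5) and -2.332 (WT 6). In tpt1 they were -0.883 (tpt1 1) and -0.898 (tpt1 2), -1.101 (tpt1 3) and -1.095 (tpt1 4), and -1.407 (tpt1 5) and -1.417 (tpt1 6). Between 490 and 603 spots were at 0 in a WT sample and between 385 and 476 in a tpt1 sample. The 10 brightest spots held 26.3% to 32.2% of the summed intensity in WT and 14.5% to 19.7% in tpt1. None of these ranges overlapped (two-sided exact permutation test, p = 0.00216 for each, the smallest p that 6 against 6 samples allow when all are taken as exchangeable). Exchanging the groups only within numbers gave an exact p of 0.0312 for each, and within the 3 sets of neighbouring numbers 0.25, again the smallest possible. By the rule fixed for medians this far apart, changes of genes are given after quantile normalization, relative to the rest of the array.

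The first question was which transcripts differ between tpt1 and WT. AT-HF (HISN4), which encodes a plastid enzyme of histidine synthesis, rose 3.24-fold in tpt1, from a normalized log2 intensity of 0.50 ± 0.16 to 2.2 ± 0.18 (mean ± SD, n = 6 and 6; log2 change 1.69, SE 0.12, limma adjusted p = 3.94e-06); with each array centred on its median the log2 change was 0.94 (adjusted p = 0.0011). PSBY, a small subunit of photosystem II, fell by 1.08 on the log2 scale, from 1.19 ± 0.15 to 0.11 ± 0.09 (n = 6 and 6; SE 0.11, limma adjusted p = 3.28e-05). PRK, the phosphoribulokinase of the Calvin-Benson cycle, fell by 0.87 (SE 0.18, adjusted p = 0.0062), with a log2 change of -0.47 (adjusted p = 0.0477) on the deposited scale and -1.33 (adjusted p = 0.000127) with median centring. AT2G04700, which encodes the catalytic subunit of ferredoxin-thioredoxin reductase, fell by 1.27 (SE 0.35, adjusted p = 0.0297). Each of these 4 genes moved the same way in 6 of 6 pairs of samples with the same number. They were called by their group difference in the same samples, so this is no separate support.

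The 10 largest rises among genes with a spot of their own ran from 2.34-fold to 5.04-fold, with a median of 3.20-fold. AT1G02020 rose 5.04-fold (log2 change 2.33, SE 0.57, adjusted p = 0.0209), AT1G07040 rose 4.75-fold (2.25, SE 0.54, adjusted p = 0.0194) and AT4G12270 rose 4.69-fold (2.23, SE 0.49, adjusted p = 0.0105). These 3 genes were dim in WT, with values above 0 in 4, 4 and 5 of the 6 WT samples, and the samples at 0 do not enter the fold. AT1G02020 had no WT value above 0 in numbers 3 and 4, and with the sample number as a block its log2 change was 2.93 (adjusted p = 4.16e-05). LpxA, named for a bacterial enzyme of lipid A synthesis, rose 3.31-fold (adjusted p = 0.036), AT2G46300 rose 3.17-fold (adjusted p = 0.000828) and AT2G35450 rose 2.60-fold (adjusted p = 6.94e-05). GH9B16, of glycosyl hydrolase family 9, rose 2.34-fold (adjusted p = 0.0413). AT4G31530 was the brightest of the 10, at 4.64 ± 0.14 in WT and 6.10 ± 0.21 in tpt1 (n = 6 and 6; 2.76-fold, adjusted p = 1.99e-05), and AT3G06200 rose 2.72-fold (adjusted p = 0.0233). Both calls were lost with median centring: AT4G31530 had a log2 change of -0.04 (adjusted p = 0.926) and AT3G06200 one of 0.49 (adjusted p = 0.419).

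The 10 largest falls ran from 1.90-fold to 2.48-fold, with a median of 2.1-fold. AT5G19050 fell by 1.31 on the log2 scale (SE 0.34, adjusted p = 0.0234), and ILA, also called ILITHYIA, fell by 1.3 (SE 0.20, adjusted p = 0.000828). AT5G03900 fell by 1.07 (SE 0.20, adjusted p = 0.00395), AT3G51510 by 1 (SE 0.23, adjusted p = 0.0124) and AT3G14890 by 0.96 (SE 0.21, adjusted p = 0.01). AT5G19940 fell by 1.15 (SE 0.33, adjusted p = 0.036) and AT3G22150 by 1.05 (SE 0.27, adjusted p = 0.0263). AT5G55580 (mTERF9), of the family of organellar transcription termination factors, fell by 0.92 (SE 0.26, adjusted p = 0.0362). With PSBY and AT2G04700 these make up the 10. On the deposited scale, where the median of all tested spots was higher in tpt1 by 0.86, the same 10 genes had log2 changes from -0.76 for PSBY to -0.10 for AT5G19940, and PSBY alone of them passed the threshold.

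**Figure D1:**
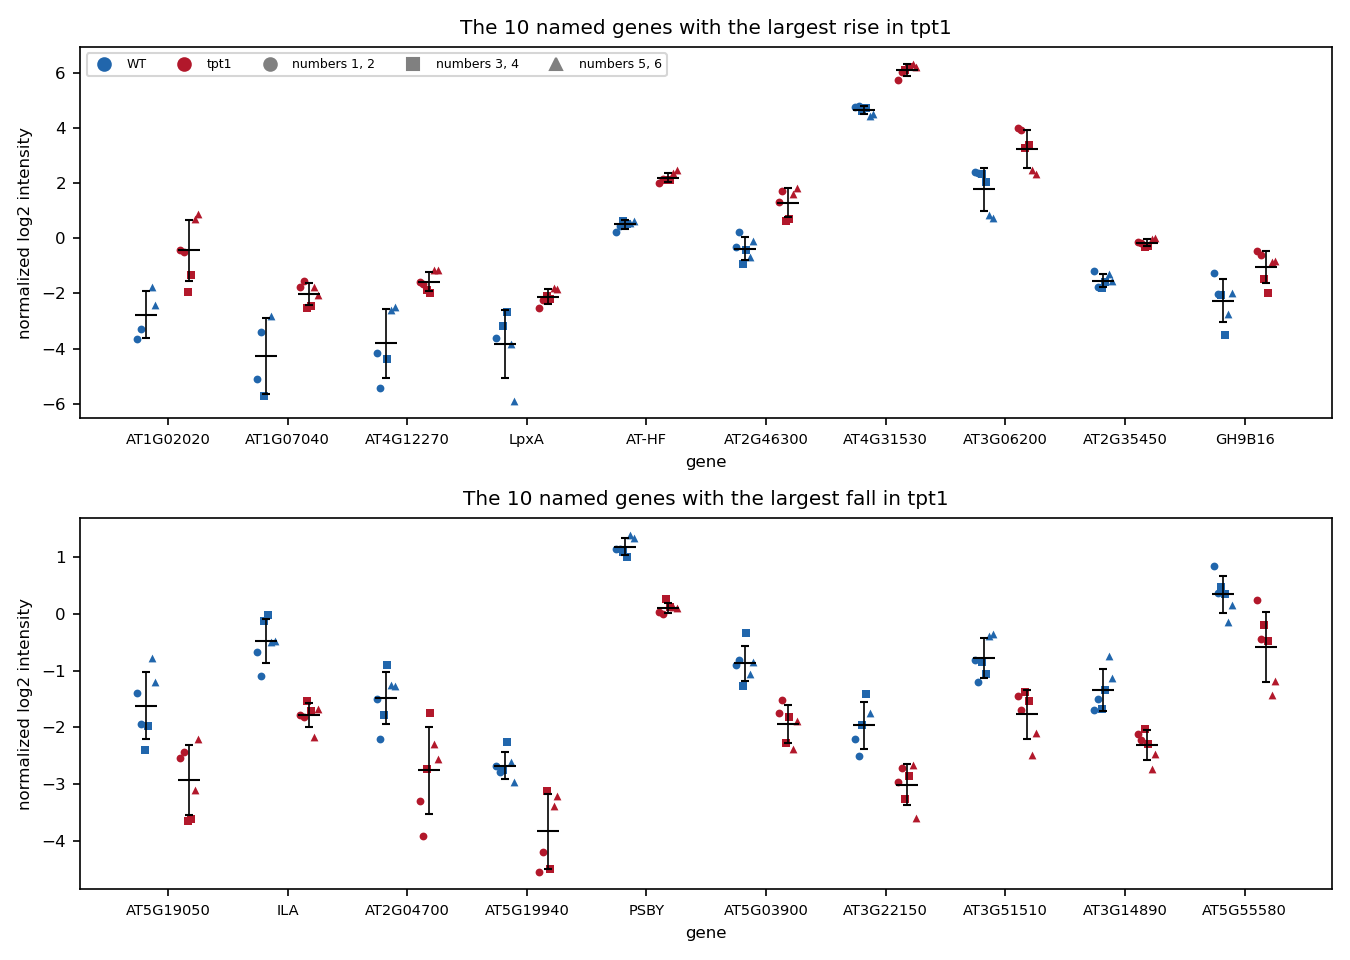
Normalized log2 intensity (vertical axis) of the 10 genes with the largest rise (upper panel) and the 10 with the largest fall (lower panel) in tpt1; each point is 1 sample, blue for WT and red for tpt1, shaped by number pair, and the black bars are the mean ± SD of the samples above 0. The groups are separated most clearly against their spread for AT-HF and AT4G31530 above and PSBY below, while AT1G02020, AT1G07040, AT4G12270 and LpxA have 4 or 5 WT points spread over more than 1 log2 unit.

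Of 2849 spots tested, 364 passed an adjusted p of 0.05, 182 higher and 182 lower in tpt1. Among spots of 1 gene, 50 were higher and 26 lower of 570 tested. With the sample number as a block, 906 spots passed, 363 of the 364 among them, and all 20 genes of the largest rises and falls did. With the samples of neighbouring numbers treated as repeats of each other by a random block, 122 spots passed; AT-HF, AT2G46300, AT4G31530, AT2G35450, AT4G12270, ILA, PSBY and PRK kept their calls and the 13 other called genes named above lost theirs. With those neighbours (1 and 2, 3 and 4, 5 and 6, the 3 sets) averaged to 3 values per group, limma called 351 spots with the set as a block, 258 of them among the 364, and 0 without it, where 383 had an unadjusted p under 0.05. LpxA, AT5G19940, AT3G22150, AT3G51510 and AT3G14890 lost their calls in the former, and all named genes in the latter.

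Leaving out 1 sample at a time gave 272 to 338 spots, and leaving out both numbers of a set in both groups gave 191 without numbers 1 and 2, 162 without 3 and 4, and 465 without 5 and 6. PRK lost its call without numbers 1 and 2, at a log2 change of -0.62 (adjusted p = 0.0751). Among the named and list genes still tested, 8, 6 and 3 lost their calls in these 3 fits, in that order, and 2, 0 and 0 came to pass. AT3G06200 lost its call without tpt1 1 (adjusted p = 0.0519), AT5G19050 without tpt1 3 (0.0522) or tpt1 4 (0.0528), and AT3G22150 without tpt1 3 (0.0564), WT 4 (0.0661) or WT 5 (0.0556). AT2G04700 lost it without tpt1 1 (0.0607), tpt1 3 (0.0524), WT 4 (0.0639), WT 5 (0.0556) or WT 6 (0.0508). GH9B16 kept its call only without WT 1 or tpt1 4, LpxA only without WT 2, WT 3, WT 4 or WT 6, AT5G19940 only without WT 6, tpt1 3, tpt1 5 or tpt1 6, and AT5G55580 only without WT 5, WT 6, tpt1 1 or tpt1 3. Their adjusted p in the other fits ran from 0.0506 to 0.087, 0.0504 to 0.067, 0.0552 to 0.0748 and 0.0509 to 0.0737, in that order. AT1G02020 and AT1G07040 kept their calls in the 8 fits in which enough WT values remained to test them. None of these fits removed a WT value above 0 of the gene, so dependence on a single WT value was not tested for these genes.

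The second question was whether genes of one plastid pathway moved together. Of the 393 genes in 25 lists, 25 had a spot of their own and 21 were tested: 0 were higher, 3 were lower (PSBY, PRK and AT2G04700) and 18 did not pass, and adjusted over the list alone, with the 21 genes of all lists as one list, 3 passed. With each list taken singly 4 did, the added one being PSAN, which was alone in its list. Of the same 21 genes, 4 were higher (AT3G13120, NTRC, AT3G58610 and AT4G01310) and 4 lower (PSAN, LHB1B2, PSBY and PRK) on the deposited scale. With median centring 0 were higher and 9 lower, PSAN, LHB1B2, AT1G74470, AT3G54210, ATSPS4F and PSBW joining the 3, so the tally depends on the scaling. The list members that did not pass after quantile normalization are named below because the lists are small, a choice made after their values were seen. Of the photosystem II list, PSBY fell, while PSBW had a log2 change of 0.48 (SE 0.22, adjusted p = 0.171) and PSB27 one of 0.22 (SE 0.40, adjusted p = 0.776). With median centring both turned, PSB27 to -0.35 (adjusted p = 0.522) and PSBW to -0.77 (adjusted p = 0.0258). PSBW passed as higher with the set as a block (adjusted p = 0.0299) and with the set and a random block (0.0349). It also did so without set 1 (0.79, adjusted p = 0.0417), but not with averaged neighbours and the set as a block (0.297). In the photosystem I list, PSAN had a log2 change of -0.45 (adjusted p = 0.13) that passed with the sample number as a block (adjusted p = 0.0437) but not with averaged neighbours and the set as a block (adjusted p = 0.201). It also passed without tpt1 1 (-0.56, adjusted p = 0.0429) and without set 1 (-0.68, adjusted p = 0.00801), the set in which its own change was 0.09. On the deposited scale it was at -0.62 (adjusted p = 0.0296) and with median centring at -1.48 (adjusted p = 3.26e-05). The antenna gene LHB1B2 had a change of -0.12 (SE 0.19, adjusted p = 0.743), but -0.78 on the deposited scale (adjusted p = 0.0166) and -1.64 with median centring (adjusted p = 0.00024). As a class, the 29 brightest spots had a median log2 change of -0.62 on the deposited scale (interval -0.78 to -0.44). Falls of that size in bright genes may therefore follow their brightness, and whether LHB1B2 and PSAN fell beyond it was not tested. PRK was the only tested gene of the Calvin-Benson list.

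In the thioredoxin list AT2G04700 fell, and NTRC, an NADPH-dependent thioredoxin reductase of plastids, had a log2 change of 0.83 (SE 0.40, adjusted p = 0.209) that passed with the block (adjusted p = 0.00248) and with averaged neighbours and the set as a block (adjusted p = 0.0386). The 4 tested plastid ribosomal protein genes lay between -0.42 (AT3G54210, adjusted p = 0.0928, 0.00949 with the block, and 0.105 with averaged neighbours and the set as a block) and 0.64 (AT3G13120, adjusted p = 0.178), with AT5G65220 at -0.07 and AT4G01310 at -0.02. On the deposited scale all 4 were above 0, AT3G54210 at 0.21, AT5G65220 at 0.19, AT3G13120 at 1.62 (adjusted p = 0.00522) and AT4G01310 at 0.78 (adjusted p = 0.0012). The tetrapyrrole genes CHLM and AT1G74470 had changes of -0.48 (adjusted p = 0.299) and -0.34 (adjusted p = 0.207). Both passed with the set as a block (adjusted p = 0.0349 and 0.0442), but not with averaged neighbours and that block (0.184 and 0.213). HEMA3, a tetrapyrrole gene that the fixed list leaves out, was called lower at -0.64 (SE 0.19, adjusted p = 0.0367). It was at -0.11 on the deposited scale and is named here after its values were seen. SIRB, another tetrapyrrole gene outside the list, was at 0.23 (adjusted p = 0.682), so the fall of HEMA3 does not stand for the pathway. The fatty acid synthesis genes FATB and AT1G24360 were at 0.05 and -0.15, and the amino acid synthesis genes AT3G23940 and AT3G58610 at -0.62 and 0.03. AT3G23940 did not pass in the main fit (adjusted p = 0.149) or with averaged neighbours and the set as a block (0.159). It passed with the set as a block (0.043) and without WT 3 (-0.79, adjusted p = 0.0463). AT3G52960 of the antioxidant list was at -0.58 and ATSPS4F of the sucrose list at -0.10. CHLM, AT1G24360, AT3G23940, AT3G52960 and ATSPS4F also turned above 0 on the deposited scale, at 0.37, 0.53, 0.33, 0.31 and 0.23. The 1 tested gene of the envelope transporter list was AT5G17630, a xylulose phosphate translocator. It had a log2 change of -1.26 with an SE of 0.86 (n = 5 and 5, adjusted p = 0.403). Transporters outside that list were not examined as a group. Its size depends on single samples: it was -2.02 without WT 5 (adjusted p = 0.0658) and -1.77 without tpt1 6 (adjusted p = 0.225), and 0.82 in set 3. It was -0.22 on the deposited scale. The other 13 lists, among them the 3 lists of markers of other tissues, had no tested gene.

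As sets, only the photosystem II list (3 genes) and the plastid ribosomal list (4 genes) could be tested, and neither passed. The photosystem II list had a camera adjusted p of 0.689, and an adjusted p of 0.724 with an estimated correlation. Its median log2 change of 0.22 and its mean of -0.13 differ in sign, and camera placed it lower. The ribosomal list had a camera adjusted p of 0.795 (adjusted p = 0.798 with an estimated correlation), with a median of -0.05 and a mean of 0.03. Without further normalization the photosystem II list passed as lower (adjusted p = 0.00868), as it did with median centring (adjusted p = 0.033). On the deposited scale only PSBY of its genes was below 0 (-0.76), with PSBW at 0.09 and PSB27 at 0.51. Camera called the list lower there against a median of 0.86 for all tested spots. After quantile normalization the list also passed as lower in fry, the self-contained set test of limma, at an adjusted p of 1.81e-05. That test asks whether the genes move one way on balance and does not compare them with other genes.

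The third question was the balance of higher and lower transcripts. After quantile normalization 182 of the 364 spots, 50%, were higher in tpt1, a balance that this normalization largely sets by giving all arrays one distribution. On the deposited scale 1323 spots were higher and 73 lower, 94.8% higher, and with median centring 133 were higher and 356 lower, 27.2% higher. The median log2 change of all tested spots was 0.86, 0.00 and 0.08 on the deposited, median-centred and quantile-normalized scales. All 50 genes called higher were also higher on the deposited scale, where the median of all tested spots is above 0, and 21 of the 26 called lower were lower there. With median centring 47 of the 50 and 26 of the 26 kept their direction. In 4 equal classes of mean intensity, the median deposited change was 1.02, 1.01, 0.91 and 0.48 from the dimmest to the brightest. Among the 29 brightest spots it was -0.62.

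**Figure D2:**
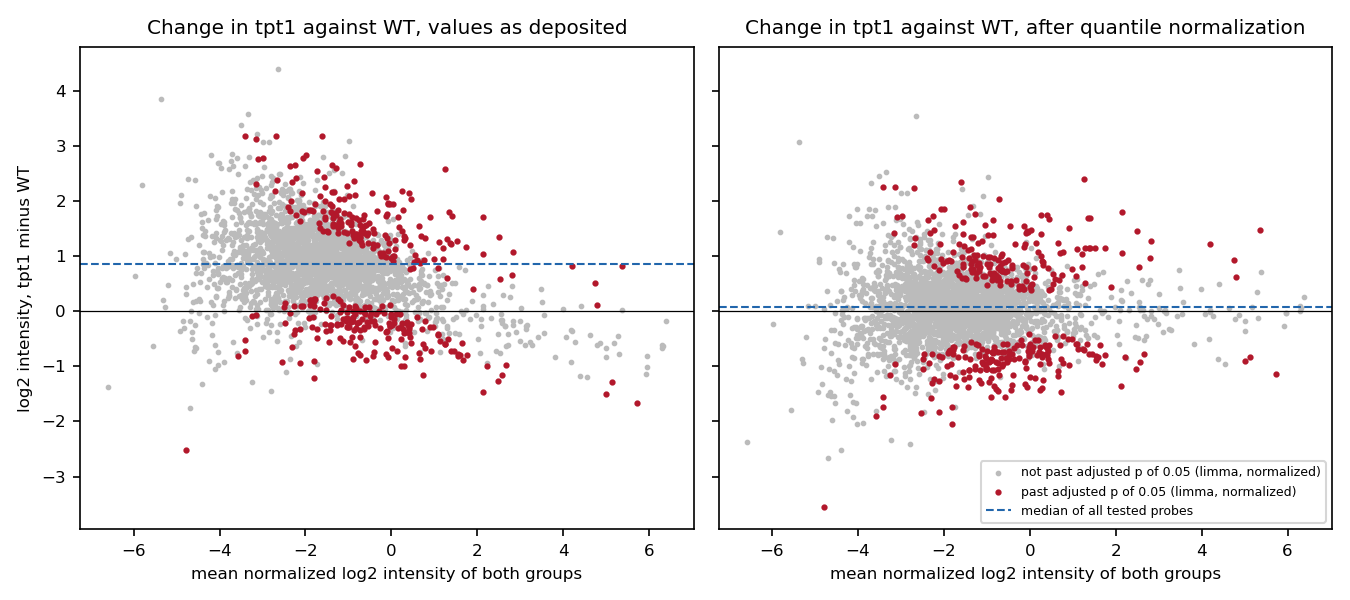
Log2 intensity in tpt1 minus WT (vertical axis) against the mean normalized log2 intensity of both groups (horizontal axis) for the 2849 tested spots, as deposited (left) and after quantile normalization (right); red spots passed an adjusted p of 0.05 in limma on the normalized values, and the dashed line is the median. The median of 0.86 on the left is 0.08 on the right, and on the left the change is smaller in the brightest of 4 equal classes of intensity (0.48) than in the dimmest (1.02).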

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

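In each group of the named genes and list genes, and for the medians and counts of zeros, the highest or lowest sample was compared with the gap expected of 4 to 6 values. Of 82 groups of values, 4 held a sample that stood apart, where 4.1 are expected by chance. AT5G17630, the xylulose phosphate translocator, was at -6.55 in WT 5 against -3.28 to -2.26 in the other WT samples above 0, and at -2.68 in tpt1 6 against -5.51 to -5 in the other tpt1 samples above 0. ATSPS4F, a sucrose phosphate synthase gene, was at 0.14 in tpt1 2 against 0.57 to 0.69 in the others. AT1G24360, of the fatty acid synthesis list, was at -1.11 in WT 6 against -0.49 to -0.17. None of these 3 genes passed the test between the groups.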

How the results depend on the processing

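The fits with the set as a block, with averaged neighbours and without a set, the floor taken over values above 0 and the combined list were chosen after seeing the data; the planned floor at a percentile of each array was 0 and was not run, nor was any alternative for TPT. The 364 spots stayed within 1.5 times with median centring (489), with the filter, the pseudocount, no trend, a robust prior, array weights, blocks of numbers 3 apart, the floor, averaged neighbours with the set as a block, without set 3, at 1.5-fold and by an exact rank-sum test (325 spots), and ran from 272 to 338 without 1 sample, with 46.8% to 53.6% higher. The count was 1396 on the deposited scale (94.8% higher, and 93.7% with the sample number as a block), 906 with the replicate block, 866 with the set block, 767 with the set and a random block, 122 with neighbours as a random block (38.5% higher), 0 with averaged neighbours and no block, 191 without set 1, 162 without set 2 and 144 at an adjusted p of 0.01. The share higher was 27.2% with median centring and 55.8% with averaged neighbours and the set as a block. Of the lists, 1 passed instead of 0 on the deposited scale, with median centring, in fry and with the combined list, where 1 was the combined list itself, a call lost with an estimated correlation (adjusted p = 0.0808), the replicate block (0.0579) or averaged neighbours (0.0915 with the set as a block, 0.0671 without). The combined list also lost its call with array weights (0.0772) and without set 3 (0.142). Fewer samples or fewer independent values may lower a count, but without set 3 the count was 465. The cause of the lower counts was not tested. The replicate block changed the call of PSAN, NTRC, AT3G54210 and the second spot of AT2G25870, all to past the threshold, and of no other gene named here; of these, NTRC alone also passed with averaged neighbours and the set as a block; it changed no call of a list as fixed. By signal, 8 spots were higher and 10 lower in the dimmest of 4 equal classes of intensity, and 92 and 93 in the brightest; whether dim signal lowers the count was not tested.

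On the deposited scale 8 genes turned from below to above 0: AT5G65220 (0.19), AT3G54210 (0.21), AT3G52960 (0.31), CHLM (0.37), AT3G23940 (0.33), ATSPS4F (0.23), AT1G24360 (0.53) and AT4G01310 (0.78, adjusted p = 0.0012). Of the genes that kept their sign there, PSAN (-0.62), LHB1B2 (-0.78), AT3G13120 (1.62), NTRC (1.63) and AT3G58610 (0.96) came to pass. Median centring turned AT4G31530 (-0.04), PSB27 (-0.35) and PSBW (-0.77), and with it PSAN (-1.48), AT3G54210 (-0.65), AT1G74470 (-1.14), ATSPS4F (-0.64) and LHB1B2 (-1.64) came to pass as lower. The pseudocount turned FATB (-0.32) and AT3G58610 (-0.06), and array weights AT5G65220 (0.04), LHB1B2 (0.0021) and AT3G58610 (-0.03). With averaged neighbours FATB was at -0.02 with and without the set block. AT4G01310 was at 0.13 without set 1 and 0.02 without set 2, AT3G58610 at -0.09 without set 2 and -0.09 without set 3, and without set 3 AT5G65220 was at 0.18 and LHB1B2 at 0.06. Without 1 sample, the changes ran from -0.30 to 0.16 for AT5G65220, -0.54 to 0.49 for FATB, -0.09 to 0.17 for AT3G58610 and -0.12 to 0.08 for AT4G01310.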

Other observations

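The tests of the combined list, of one scale factor, of the ceiling, of shared spots and of shared plants were chosen after the results they bear on had been seen; the tests of background and of other splits were not, apart from the 9 splits that follow the sets. The random draw of splits reported here was made after earlier draws had been seen, which included 2 of those 9, with 293 and 180 called spots. When the photosynthesis lists (photosystems, antenna, electron transport and Calvin-Benson cycle) were joined and spots whose annotated genes all belong to one list were counted, 8 spots were tested. Of these 3 were lower in tpt1 and 0 higher, with a median log2 change of -0.52: PSBY, PRK and a spot shared by 3 antenna genes, which fell by 0.60 (SE 0.17, adjusted p = 0.0361). The joined list was lower in camera (adjusted p = 0.0239), but not with an estimated correlation (adjusted p = 0.0808), with the sample number as a block (adjusted p = 0.0579), or with averaged neighbours, with the set as a block (adjusted p = 0.0915) or without it (0.0671). Nor did it pass with array weights (adjusted p = 0.0772) or without set 3 (0.142). Its median was -0.28 on the deposited scale and -1.14 with median centring. A spot shared by 2 tetrapyrrole genes fell by 1.05 (SE 0.32, adjusted p = 0.0477), and the tetrapyrrole list with it did not pass (camera adjusted p = 0.0925, and adjusted p = 0.153 with an estimated correlation). It did pass as lower on the deposited scale (0.0442), with median centring (0.0275), with the set as a block (0.0363) and with the set and a random block (0.0193), but not with the sample number as a block (0.0579) or with averaged neighbours, with the set as a block (0.0915) or without it (0.148).

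Some spots were listed at 0 in one group and above 0 in the other, which the test leaves out. There were 23 spots at 0 in at least 5 WT samples and at most 1 tpt1 sample, and 2 the other way. Of 1-gene spots, AT4G17260 was at 0 in 5 WT and 0 tpt1 samples, AT4G05030 and AT1G35340 each in 6 WT samples and 1 tpt1 sample, and AT5G13260 in 1 WT and 5 tpt1 samples. The tpt1 values of AT4G05030 above 0 ran from 0.001 to 0.204 on the scale that ends at 100. These genes were picked by their values, and the excess toward tpt1 goes with its smaller number of spots at 0.

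On the deposited scale far more spots were higher than lower in tpt1. One scale factor per array, acting alone, would move all intensities alike, but the medians of the log2 change in 4 equal classes of intensity lay 0.54 apart. They were 1.02, 1.01, 0.91 and 0.48 from the dimmest class to the brightest, so a scale factor together with another cause stays open. A higher background in tpt1 would add the same amount at all intensities, but the difference in the third class was 3.5 times that in the first (95% bootstrap interval 3.21 to 3.82). WT readings held at the ceiling would raise tpt1 over WT only in spots that reach it, and only 7 spots had a reading there in any sample. These are too few to account for the 1323 spots called higher. That 0 of the 1323 had a WT reading there adds little, since so few spots could count. A response that bends with brightness, the unstated scaling before deposit, or transcripts of the brightest genes that make up less of the RNA in tpt1 may each account for it, and none of these was tested.

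The numbered samples deviate together across the groups. Plants or a day shared by a set alone would give neighbouring numbers the same correlation, but the same number exceeded its neighbour by 0.18, 0.41 and 0.15 in the 3 sets (95% bootstrap intervals over spots 0.14 to 0.21, 0.35 to 0.47 and 0.11 to 0.19). A spot or reading position shared by WT and tpt1 may account for the pairing, but that 12 of 12 samples correlated best with their own number is the observation that raised the idea and does not test it. What a number marks stays open, and a biological source for the pairing was not tested.

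The count of called spots was set against other splits of the samples. Of 100 splits of the 12 samples, the real one included, 1 gave as many as 364 spots. That count takes the samples as exchangeable. Most of these splits part neighbouring numbers, which correlated at 0.63 within a random block, so the count does not exclude chance. The 9 other splits that keep the samples of a group and set together were also fitted, and the highest of the other splits fitted called 293. That split set WT 1, tpt1 1, WT 2, tpt1 2, WT 3 and WT 4 against the rest, so the sets are a structure of the samples, and the real split with the set as a block called 866. With the sample number as a block, 1 of the 32 splits that part every numbered pair gave as many as 906, and the highest other gave 2. If the 3 sets are the independent units, the splits are too few to exclude chance.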
